A study of Gallus gallus with 4 samples.

How the data were processed

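Poly(A) RNA of the right heart ventricle was sequenced on an Illumina HiSeq 2000, per the labels, in 2 Ascitic and 2 Healthy libraries of 39-day-old chickens. The authors deposited 1 table per library, with an FPKM per locus, the bounds of its confidence interval and a status, per the file headers, which have the format of a Cufflinks gene table. The aligner, the tool versions, the genome build, the annotation and any scaling between libraries are not given in the sources used here. Per the deposited tables, 76.4% to 77.4% of rows in a library carry an ID assembled in that library alone, and the rest an Ensembl gene ID. No gene names stand beside the IDs. The RefSeq gene names at hand came with an empty column for Ensembl IDs, so 0 of the 7107 Ensembl IDs could be matched. The 40 gene lists with 1304 members that were fixed before the data were examined, cell type markers among them, therefore had no matched members, and no list was tested. Between 10.7% and 11.0% of rows in a library have an FPKM outside their own interval.

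In each library 240 to 247 IDs occur on more than 1 row, and rows that share an ID were summed. Locus starts in the files count from 0 and were raised by 1, so that positions are 1-based. Since assembled IDs do not carry over between libraries, loci were joined by position. Loci of different libraries were linked where their overlap was at least 80% of the longer span, and linked sets with exactly 1 locus in each library were kept, 15653 in all. This rule was set after the files were seen and before any test. The 9725 joined loci with a mean FPKM of at least 1 over the 4 libraries were tested, 1537 of them with an Ensembl ID in some library. They held 76.4% to 79.0% of the FPKM total of a library. Of these loci, 5896 overlapped no other locus in any library. As a second measure, all loci that overlap each other were merged into groups and their FPKM summed, which gave 11111 groups with a mean of at least 1. An FPKM sum over loci of unequal length does not keep the number of fragments.

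The test was fixed before the data were examined. It was limma 3.58.1 in R 4.3.3, on log2(FPKM + 1) of the values as deposited, with a moderated test and a mean-variance trend, two-sided, with no covariate, and Benjamini-Hochberg adjustment to 0.05. A fold change on this scale understates the change of low values. Values with a failed or low-data status were used as given, and a locus listed at 0 can be a failed estimate. FPKM values are not counts, so no count model was fitted. Relative depth was read from the steps between the low values, under 0.08 FPKM, of Ensembl genes found in both libraries of a pair. In 17.9% to 26.9% of such genes the ratio fell in the commonest step. Single values were compared by an exact permutation test over the 6 placements of 2 of 4 libraries. Chromosomes were tested as sets with camera at a preset correlation of 0.01, with an estimated correlation and with fry. The shift of Z-linked loci between 2 libraries was set against 10000 random lists of autosomal and unplaced loci of the same size, matched on mean value. Tables were joined with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9.

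The test was tried on simulated data with the means of these 9725 loci and 200 loci changed by known amounts, 50 of each size, in 20 draws. The spread of each locus was drawn anew from the distribution that limma had fitted to these loci, with normal noise. In these draws the test called 8.30% of loci changed by a log2 of 1, 80.2% at 2, 95.6% at 3 and 97.9% at 4. Of the calls in the draws, 4.83% were false, and a draw had a median of 149.5 calls. Only means and spread were taken from the data. Loci listed at 0 throughout a group, fragments divided among overlapping loci and FPKM outside their intervals were not modelled. The simulated shares therefore cannot give the power or the false share for the real calls. Recovery with fewer changed loci was not simulated.

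The rule for named genes, fixed before the data were examined, took up to 15 genes with a gene symbol per direction by size among those past the threshold, members of the fixed lists, a set of cardiac and hypoxia genes, and the 5 genes of highest mean FPKM. With no symbols at hand, only the last part could be followed, for tested loci in place of genes. The loci past the threshold, and the 2 of smallest p per direction among loci that overlap no other, were named after their values were seen. Alternatives fixed beforehand were other pseudocounts, filters and scalings, no trend, a robust fit, the replicate number as a block, each library left out, the highest row kept per ID, a fold threshold, and Z- and W-linked loci left out. Those added after seeing the data were other overlaps for the join, rows sharing an ID kept apart, loci that overlap no other, loci above 0 in all libraries, loci of at least 200 bp, interval midpoints, sums of overlapping loci, and the tests by chromosome.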

Results

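Messenger RNA of the right heart ventricle was measured in chickens of an Iranian native meat-type breed, 39 days old, in 2 libraries labelled Ascitic and 2 labelled Healthy. Ascites in meat-type chickens is the build-up of fluid in the body cavity that follows raised pressure in the lung arteries and failure of the right ventricle. Cold raises the demand for oxygen and is used to bring the disorder out. All birds were kept in the cold from day 21, per the labels, which give day 54 as its end, later than the stated age of 39 days. The deposited values are FPKM, a fragment count scaled for transcript length and for the size of the library, given per locus and library without counts. They summed to 574175 in Ascitic replicate 1, 547839 in Ascitic replicate 2, 612071 in Healthy replicate 1 and 624742 in Healthy replicate 2, over 22901 to 23320 rows per library. The total number of fragments is unknown, but the steps between low values put the depths of the other 3 libraries at 1.03, 1.01 and 1.03 times that of Ascitic replicate 1, in the same order. The labels do not say whether the libraries came from separate birds or from pools, so the p-values measure only the spread between these libraries, which may be technical.

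The comparison asks which transcribed loci of the right ventricle differ between ascitic and healthy chickens under the same cold challenge. Among 9725 loci matched across the 4 libraries, 2 passed the threshold as higher and 6 as lower in the Ascitic libraries (limma moderated test, Benjamini-Hochberg adjusted p under 0.05, n = 2 libraries per group). All 8 overlapped another assembled locus, and 7 of them were listed at 0 in both libraries of a group. None of the 5896 loci that overlapped no other locus passed (limma, smallest adjusted p = 0.114). Of them, 386 had an unadjusted p under 0.05, against 311 and 161 in the other 2 ways to split the 4 libraries (limma). The files pair no locus with a gene name, so loci are given by chromosome, start and end, counted from 1 and covering the spans joined from the 4 libraries, and the genome build is not given in the sources used here.

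The 2 loci that rose in the Ascitic libraries lay on an unplaced scaffold and on chromosome 2. The first, AADN03020085.1:1-1396, had an FPKM of 20.8 and 34.0 in Ascitic replicates 1 and 2 and was listed at 0 in both Healthy libraries (limma, adjusted p = 0.0184). An overlapping locus of the same scaffold was present in every library, with a mean FPKM of 41.1 ± 13.3 (SD, n = 2) in Ascitic and 71.7 ± 10.9 (SD, n = 2) in Healthy. The second, 2:63302984-63336466, had an FPKM of 13.2 and 10.2 in the Ascitic libraries and was listed at 0 in the Healthy ones (limma, adjusted p = 0.0184). Here too the overlapping locus was lower in Ascitic, at 200 ± 1.87 against 242 ± 15.8 (mean FPKM ± SD, n = 2 each). The sums of all loci that overlap there differed by a log2 of -0.058 ± 0.19 at the first and -0.19 ± 0.16 at the second (SE). Neither sum passed (limma, adjusted p = 0.990 and 0.926, the highest of their alternatives, whose lowest was 0.00775 for both). At the second, the overlapping locus makes up most of the sum, which therefore says little of the called locus.

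Of the 6 loci that fell in the Ascitic libraries, 5 were listed at 0 in both of them. The locus 17:8607850-8614033 reached 10.6 and 11.0 FPKM in Healthy replicates 1 and 2 (limma, adjusted p = 0.0184). The overlapping locus, which begins at 8490013, had 14.6 and 10.2 FPKM in the Ascitic libraries and 10.8 and 7.55 in the Healthy ones, and all loci that overlap there, minor ones included, together differed by a log2 of -0.49 ± 0.22 (SE; limma, adjusted p = 0.867, the highest of its alternatives, whose lowest was 0.00775). A 118-bp Ensembl gene, ENSGALG00000025648 at 7:25702714-25702831, had 10.3 FPKM in each Healthy library (limma, adjusted p = 0.0184), and it lies inside a longer locus, within 25580806 to 25726775, that was detected in all 4 libraries. A 139-bp Ensembl gene, ENSGALG00000017828 at 12:19462147-19462285, had 24.9 and 15.7 FPKM in the Healthy libraries (limma, adjusted p = 0.0184), inside an abundant locus whose assembled span differed between the groups. That locus ran from 19460962 to 19466113 in Ascitic, with 1135 and 1021 FPKM, and from 19460962 to 19462997 in Healthy, with 1437 and 1297. For both genes the Healthy FPKM stood above the confidence interval deposited beside it, whose upper bounds were 2.54 and 2.55 for the first and 6.46 and 4.95 for the second. With interval midpoints neither was called: the first had a mean under the filter, and the log2 difference of the second went from -4.38 to -2.10 (limma, adjusted p = 0.0756, within 0.00775 to 0.885 over its alternatives). The other loci listed at 0 in Ascitic were AADN03010873.1:3381-8631, with 7.72 and 11.2 FPKM in Healthy, and 1:169764861-169765994, with 7.53 and 5.88 (limma, adjusted p = 0.0329 for each). With overlapping loci summed none of these 4 passed. The log2 differences of the sums at the 118-bp gene, the 139-bp gene and AADN03010873.1:3381-8631 were -1.23, -0.38 and -0.49 (limma, adjusted p = 0.431, 0.885 and 0.806). At the 139-bp gene the overlapping locus makes up nearly all of the sum, which therefore says little of the gene. At 1:169764861-169765994 the sum, which takes in further loci up to 169787231, differed by 0.25 ± 0.34 (SE; limma, adjusted p = 0.960). These were the highest adjusted p of their alternatives, whose lowest were 0.00775 for both genes and 0.0141 for the other 2 loci.

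**Figure D1:**
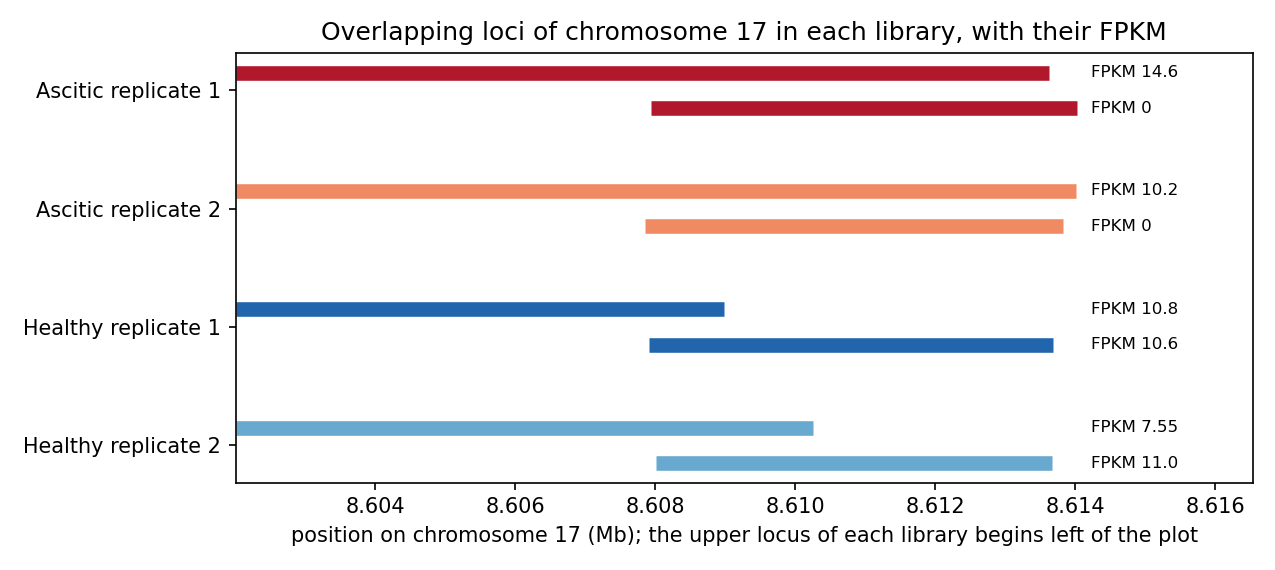
Assembled loci at the right end of the called region of chromosome 17, 1 row of bars per locus in each of the 4 libraries, against position in Mb, with the deposited FPKM of each locus at the right. The lower bar is the called locus, listed at 0 in both Ascitic libraries, where the upper locus ends at 8613621 and 8614016, and at 10.6 and 11.0 FPKM in the Healthy libraries, where the upper locus ends at 8608978 and 8610260.

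The remaining locus that fell, AADN03017166.1:86-2493, was abundant in every library, but its assembled span differed between the groups. It began at 86 and 87 in the Ascitic libraries and at 400 in both Healthy ones, where a separate short locus covered the left end. Its FPKM was 731 ± 157 in Ascitic and 5455 ± 756 in Healthy (SD, n = 2), a log2 difference of -2.91 ± 0.23 (SE) on the log2(FPKM + 1) scale (limma, adjusted p = 0.0464). All 4 values lay above the intervals deposited beside them, which ran from 140 to 239 over the Ascitic libraries and from 139 to 218 over the Healthy ones. With the midpoints of those intervals in place of the FPKM, the log2 difference was 0.084 and the call ended (adjusted p = 0.994 in limma, the highest of its alternatives, whose lowest was 0.0144).

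Among loci that overlapped no other and were above 0 in all libraries, the strongest differences did not pass the test, and they are given as values. They were chosen after their values were seen, as the 2 of smallest p in each direction. The locus 2:121225584-121229023 had 284 ± 63.2 FPKM in Ascitic and 62.2 ± 1.87 in Healthy (SD, n = 2), a log2 difference of 2.16 ± 0.20 (SE; limma, adjusted p = 0.0708). The locus 9:2931951-2940325 had 26.4 ± 2.55 FPKM in Ascitic and 5.70 ± 1.00 in Healthy, a log2 difference of 2.04 ± 0.20 (SE; limma, adjusted p = 0.0729). With the robust form of the same moderated test these 2 passed, at adjusted p = 0.0352 and 0.0422 (limma), the lowest of their alternatives, whose highest were 0.282 and 0.301. Without Ascitic replicate 1 the log2 differences of these 2 loci were 2.39 and 1.94. In the other direction, a 119-bp Ensembl gene at 2:45053822-45053940 had 159 and 123 FPKM in the Ascitic libraries against 6970 and 2170 in the Healthy ones. Its log2 difference was -4.78 ± 0.55 (SE; limma, adjusted p = 0.135, and 0.0982 to 0.443 over its alternatives with all 4 libraries). Leaving out Healthy replicate 1 gave the gene a log2 difference of -3.94, and leaving out Healthy replicate 2 gave -5.63. All 4 of its values lay above their intervals, which were 5.08 to 13.8 and 2.87 to 10.4 in Ascitic and 288 to 352 and 86.7 to 120 in Healthy. The locus 20:4159058-4170387 had 3.09 ± 0.68 FPKM in Ascitic and 11.0 ± 0.15 in Healthy. Its log2 difference was -1.57 ± 0.20 (SE; limma, adjusted p = 0.168, and 0.0974 to 0.443 over its alternatives with all 4 libraries). Its value was that of a single row only in Healthy replicate 2, and elsewhere it sums rows that share an ID. With those rows kept apart no locus of this span was among those tested.

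**Figure D2:**
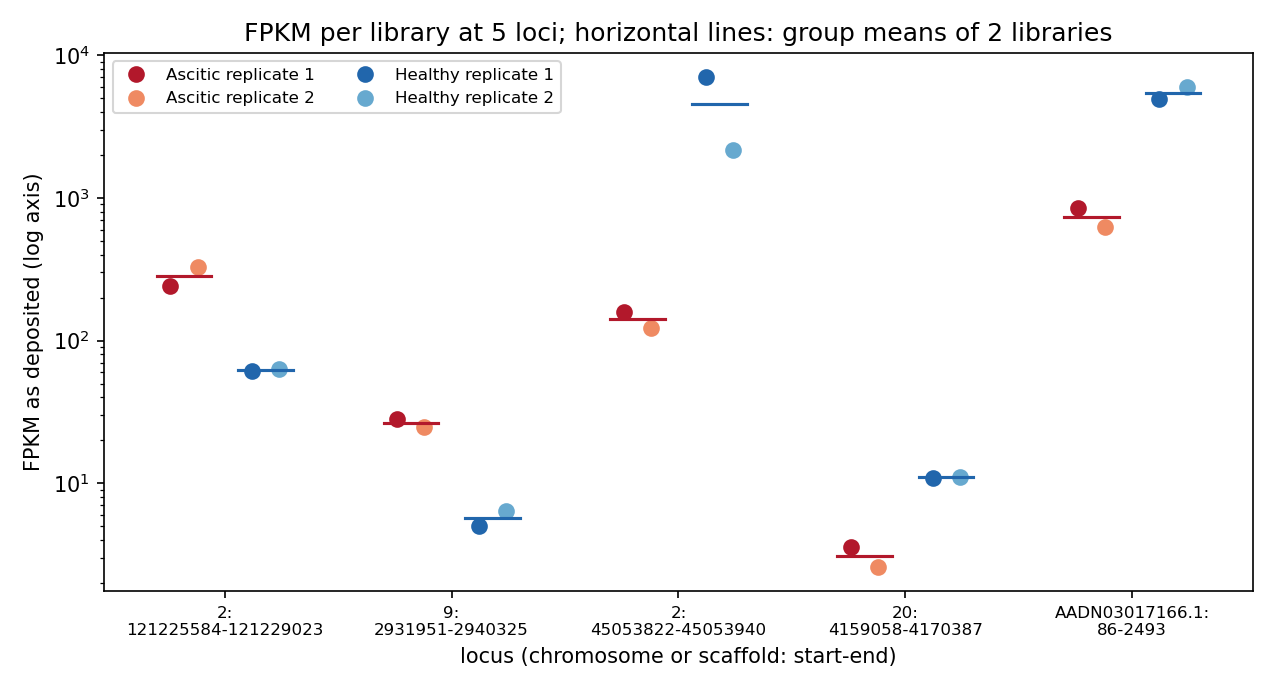
FPKM as deposited, on a log axis, of 5 loci in the 4 libraries, with points for single libraries and horizontal lines for the means of 2 libraries. At each locus both Ascitic points lie on the same side of both Healthy points, from 240 and 329 against 60.8 and 63.5 at 2:121225584-121229023 to 842 and 620 against 4921 and 5990 at AADN03017166.1:86-2493, the only 1 of the 5 that passed the test.

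The most abundant of the tested loci had similar values in both groups, and none passed the test. Loci left out by the join were not ranked, and no row lay on a chromosome labelled as mitochondrial. The locus with the highest mean, 15:6028493-6032632, had 5741 ± 858 FPKM in Ascitic and 6154 ± 104 in Healthy (SD, n = 2), a log2 difference of -0.11 ± 0.21 (SE; limma, adjusted p = 0.994). The next 4, at 2:3420143-3455225, 5:31546121-31552902, 1:47886140-47891373 and 1:76434647-76437498, differed by a log2 of 0.16, -0.22, -0.29 and -0.07 with SEs of 0.18 to 0.21, and none had an adjusted p under 0.959 (limma). The sign of the first and of the last turned when libraries were scaled to the same total. Over all rows of a library, tested or not, the 10 highest values made up 8.39% to 9.25% of the FPKM total.

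Lower values in Ascitic were more frequent than higher ones across all tested loci, but this balance rested on Ascitic replicate 2 and moved with the scaling. In the values as deposited the median log2 difference was -0.08, and 391 loci were lower and 194 higher at an unadjusted p under 0.05 (limma). Scaling each library to the same total moved the median by 0.12 to 0.05 and turned the balance to 235 lower and 373 higher, with 5 calls lower and 3 higher in place of 6 and 2. Scaling to the upper quartile left it about even, at 337 lower and 315 higher, as did the median of ratios, at 327 and 329, each with 5 calls lower and 3 higher. As deposited, Ascitic replicate 2 had a median log2 difference of -0.20 from Healthy replicate 1 and of -0.17 from Healthy replicate 2. For Ascitic replicate 1 these medians were 0.009 and 0.049. Both Ascitic libraries lay on the same side of both Healthy libraries in 33.7% of tested loci, where chance gives 33.3%.

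No chromosome passed a test as a whole. Of 29 chromosomes and linkage groups with at least 20 tested loci, a grouping chosen after the data were seen, none passed in limma's camera with a preset correlation (smallest adjusted p = 0.974), with an estimated correlation (0.994) or in fry (0.737), and none had an unadjusted p under 0.05 in any of the 3. Chromosome 28 had the smallest p in camera with the preset correlation, with a median log2 difference of -0.11 over 161 loci, of which 14 were lower and 2 higher at an unadjusted p under 0.05 (camera, unadjusted p = 0.0785). With the estimated correlation the smallest was that of chromosome 26 (unadjusted p = 0.563) and in fry that of chromosome 24 (unadjusted p = 0.156), whose median was -0.14 over 99 loci. On chromosome 9, with 254 loci and a median of -0.09, 10 loci were higher and 5 lower at that p.

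The number of calls changed as single libraries were left out, where the remaining library of a group gave no spread of its own. It was 25 without Ascitic replicate 1, 28 without Ascitic replicate 2, 24 without Healthy replicate 1 and 5 without Healthy replicate 2, against 8 with all 4 libraries, and 4, 4, 8 and 1 of the original 8 loci were among them. Summing the FPKM of overlapping loci, or testing only loci above 0 in all libraries, left no call (limma), with 679 of 11111 and 594 of 9596 at an unadjusted p under 0.05. The second of these takes out 7 of the 8 called loci by its own rule, since they were listed at 0 in a whole group. Dropping the filter on low values, or raising it to a mean FPKM of 5, left no call either, with 842 of 13075 and 395 of 6360 loci at that p (limma).

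The libraries of a group were about as alike as libraries of different groups. Across the tested loci, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.960 between the Ascitic libraries and 0.968 between the Healthy ones, and 0.956 to 0.964 between libraries of different groups. Spearman's rho was 0.948 and 0.963 within the groups and 0.948 to 0.953 between them.

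Loci of the sex chromosomes differed between the libraries of each group, and the group means lay within that spread. Female birds carry a Z and a W chromosome and males a pair of Z chromosomes, and the labels do not give the sex of the birds. The 4 tested W-linked loci had a mean FPKM of 4.07 in Ascitic replicate 1, 0.541 in Ascitic replicate 2, 1.65 in Healthy replicate 1 and 2.62 in Healthy replicate 2. The locus W:153763-223268 ranged from 0.916 FPKM in Ascitic replicate 2 to 7.07 in Ascitic replicate 1. The median of 449 Z-linked loci, relative to 9272 loci on autosomes and unplaced scaffolds after centring each locus, was -0.06, 0.06, 0.10 and -0.10 on the log2 scale in the same order of libraries. Between groups, the Z-linked median log2 difference was -0.02 relative to the other loci, and neither the Z medians nor the mean W-linked FPKM differed by more than the spread between libraries (exact permutation test, two-sided, p = 1 for each; with 2 against 2 libraries the smallest p is 0.333).

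**Figure D3:**
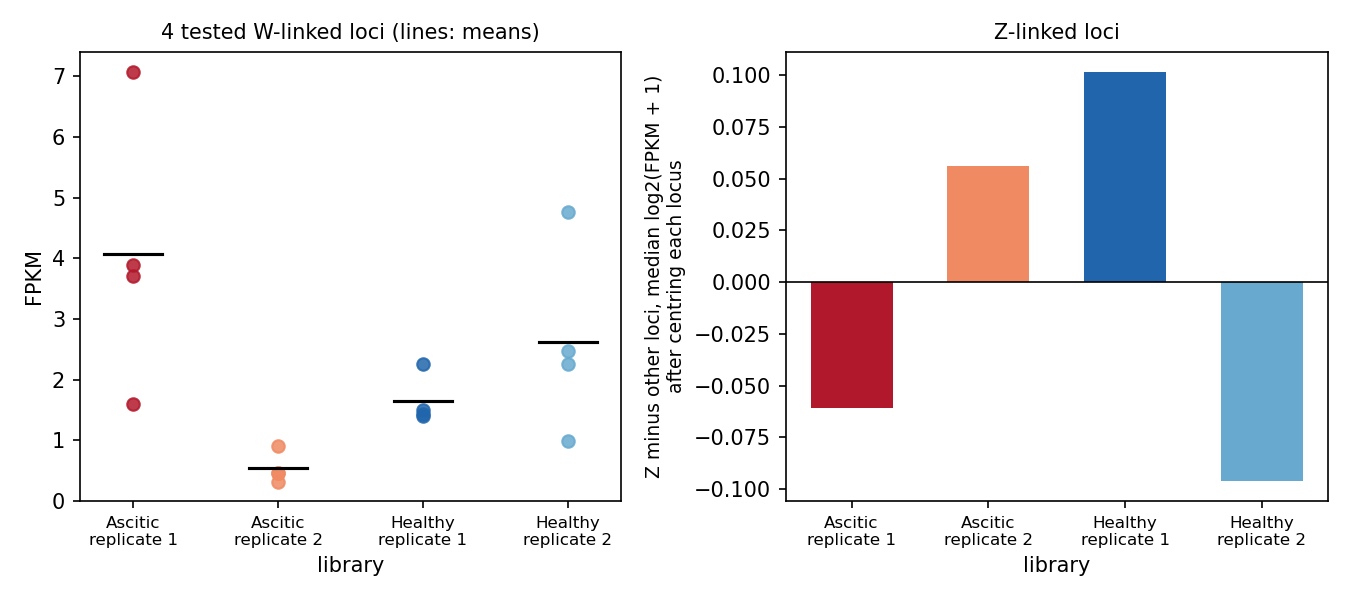
Left, FPKM of the 4 tested W-linked loci in each library, with lines at their means. Right, bars for the median of 449 Z-linked loci relative to the other loci, on the log2(FPKM + 1) scale after centring each locus. In each group the library with the higher W-linked mean, 4.07 in Ascitic and 2.62 in Healthy, has the lower Z-linked median, -0.06 and -0.10.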

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

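The count of 8 called loci was the least stable value. It fell to 0 with no filter on low values (842 of 13075 loci at an unadjusted p under 0.05, limma), with a mean FPKM of at least 5 (395 of 6360), and, added after seeing the data, among loci that overlap no other, among loci above 0 in all libraries and for sums of overlapping loci. The filter on overlap takes out all 8 called loci by its own rule, and that on values above 0 takes out 7 of them. The count was 5 with quantile normalization (4 lower, 1 higher), 14 with the robust fit and 1 where positions had to be identical, which tested 2657 loci. With the replicate number as a block it was 0 (limma, 628 loci at an unadjusted p under 0.05). Over all tested loci, deviations of same-numbered libraries were nearly uncorrelated (correlation 0.0444), which cannot exclude a pairing at some loci. The labels state no pairing. Leaving out 1 library gave 5 to 28 calls, with the lone library assumed to vary like the others. Under the other 14 single-setting alternatives it was 7 to 12, but the loci called were not always the same. With interval midpoints only 5 of 12 calls were among the original 8 loci, and the rest were not called with the deposited FPKM. With an overlap of 50% for the join, 5 of 9 calls were original loci of the same span. The cause was not tested in any of these settings. The sums of overlapping loci at AADN03020085.1:1-1396, 2:63302984-63336466 and 1:169764861-169765994 differed by -0.058, -0.19 and 0.25. Their signs were opposite to those of the called loci, but they lay within or near their SEs of 0.19, 0.16 and 0.34. Interval midpoints turned AADN03017166.1:86-2493 to 0.084. Of the most abundant loci, neither of which was called anywhere, 15:6028493-6032632 turned to 0.033 when libraries were scaled to the same total and to 0.041 with quantile normalization, and ran from -0.26 to 0.045 as single libraries were left out. The locus 1:76434647-76437498 turned to 0.075 and 0.25 under the same 2 settings, to 0.013 with the upper quartile and to 0.027 with the median of ratios, and ran from -0.21 to 0.077. The Z-linked median relative to other loci ran from -0.11 to 0.10 as single libraries were left out. The mean r within groups exceeded that between groups by 0.00449, by 0.00856 at a pseudocount of 0.1 and by 0.00231 with no filter on low values. No chromosome passed under any of the 3 set tests. The alternatives for gene lists, and camera on ranks, were not run, because no list had matched members. With no counts at hand, depth limits the low values to an unknown extent.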

Other observations

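All explanations and tests in this part were chosen after the values were seen. Merging overlapping loci brought in 2074 groups with no locus in the comparison above, none of which passed the threshold. Of the groups described next, that on chromosome 16 was among them, while those on chromosomes 23 and 4 held a tested locus. On chromosome 23, the locus 23:5293424-5406841 had 5.19 and 3.89 FPKM in Ascitic and 2.30 and 1.84 in Healthy, and a separate locus at its right end, reaching 5407956, was assembled only in the Healthy libraries, with 22.6 and 28.3 FPKM. On chromosome 16, a locus of 104 to 109 bp beginning at 355871 was assembled only in the Healthy libraries, with 399 and 180 FPKM and interval upper bounds of 11.9 and 9.08, while Ascitic replicate 1 had a longer locus there with 4.76 FPKM. The locus 4:13861296-13934946 had 11.2 and 6.61 FPKM in Ascitic and was listed at 0 in Healthy, where the status of both estimates was FAIL. In all, 84 merged loci were assembled in both Ascitic libraries and no Healthy one, and 96 in the reverse, while the other 2 ways to split the libraries gave 129 and 72, and 154 and 67. The 123 tested loci shorter than 200 bp had a median log2 difference of -0.23, against -0.06 for loci of 200 to 2000 bp. These short loci also varied more within groups. The SD of their log2 difference between replicates was 1.51 in Ascitic and 2.09 in Healthy, against 0.60 and 0.50 for the longer ones.

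The called loci listed at 0 may reflect how fragments were divided among overlapping loci. Of tested loci listed at 0 in some library, 91.5% overlapped another locus, against 38.7% of loci above 0 in all libraries (Fisher's exact test, p = 7.39e-36). That test treats loci as independent. A joined locus also had to be listed in every library, which may itself favour overlapping loci among those at 0, so this contrast is weak support. In 5 of the 7 called loci listed at 0 the overlapping loci differed the other way (exact binomial test, p = 0.453), in only 2 with the groups apart, which neither shows nor rules out a transfer of fragments for single loci, and a change of transcript ends with ascites stays open and untested. A difference in depth is argued against by relative depths within 1.03 times. The 4 libraries make only 3 splits, too few for a share under 0.05. The real split called 8 loci (1 split with as many), and the highest of the others called 2 (limma). For sums of overlapping loci the real split called 0 and the others 2 each (limma). For loci that overlap no other it called 0 and the others 1 and 0. At an unadjusted p under 0.05 the real split had 585 loci, against 537 and 236 in the others (limma). For sums these counts were 679 against 523 and 402, and for loci that overlap no other 386 against 311 and 161.

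The 4 W-linked loci differed within groups, by a median of 7.80 times between Ascitic replicates 1 and 2 and 1.67 times between Healthy replicates 2 and 1. Relative depths were within 1.03 times, but FPKM is already scaled for library size, so setting these ratios against depth cannot test depth as a cause. Different shares of RNA from female birds are a candidate explanation. Where W-linked values were higher, Z-linked ones were lower, by a log2 of -0.13 in Ascitic and -0.17 in Healthy, and 0 of 10000 matched random lists were as low in either group. Such lists treat loci as independent and cannot show how far the loci of a whole chromosome shift together between libraries. One W-linked locus, W:19458-138725, went the other way in Healthy, where replicate 2 had 0.655 times the FPKM of replicate 1. The labels do not give the sex of the birds, so this stays a hypothesis.

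Several strong differences rest on an FPKM far above its own confidence interval, and the step behind that gap, not stated in the sources used here, may shape them. For AADN03017166.1:86-2493 the log2 difference went from -2.91 to 0.084 with interval midpoints, so this call may rest on that step, and the 118-bp and 139-bp genes went from -3.50 to -1.18, under the filter and so not tested, and from -4.38 to -2.10. For the 119-bp gene at 2:45053822-45053940 it went from -4.78 to -4.36, which argues against the step as the whole cause, and a difference with ascites stays open. The merged loci at 2:96940770-96955365 summed to 492 and 666 FPKM in Ascitic and 4.97 and 2.40 in Healthy, and their log2 difference went from 6.99 to 1.74, so that part of it is left and its cause stays open.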
